A study of Homo sapiens with 4 samples.

How the data were processed

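LACE-seq was made from NCI-H1299 cells in 4 libraries, 2 with an antibody against P5CS and 2 with IgG, grouped by the sample titles. Nothing in the labels says whether libraries of 1 group came from separate cultures. The submitters' processing notes name fastp 0.23.2, STAR 2.7.10a and the genome build hg38, without saying which step each served. The tool that called the sites, its threshold, the use of the IgG libraries and the pooling of replicates are not given in the sources used here.

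The authors deposited 1 list of 17625 sites with chromosome, start, end, width, strand, region, annotation text and assigned gene, which hold positions and names and no measured level. The column names are those that an R peak annotation package writes, per the file headers. All 17625 starts and ends are multiples of 20 bases, and the width runs from 21 bases, which is also the median, to 2641. The site width is set by that grid, with 74.3% of sites at the smallest width, so a site places an RNA contact only to about 1 step of the grid. Sites span 441359 bases with both strands merged. The list holds no column of values per library, so the number of such columns not used is 0. The planned tests of anti-P5CS against IgG, the overlap between replicates and any ranking by score therefore could not be run, and the depth of each library is unknown. The words of sequence in the sites were not analysed here, because no genome sequence was used.

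Regions were taken from the list's region column. Genes were taken in 2 ways. Counts per assigned gene use the gene named in the list. Gene list tests use the gene spans of the RefSeq table for GRCh38.p14, with any overlap of at least 1 base on either strand, because 3465 sites (19.7%) had no symbol. Of 14160 sites with an Entrez ID 14157 matched that table, and 11 symbols differed in it. The table gives no scaffold. On 4 chromosomes 224 of its genes, RNA45SN4 among them, lie ahead of the first listed site, and none of the 224 had a site, so part of the table's positions can be those of scaffolds that the list does not cover. Of 13106 exon and intron sites, 1455 were annotated to another gene than the one assigned. RefSeq spans held 13893 sites (78.8%), and 4773 of 59716 RefSeq genes had a site, among them 2706 of 20050 protein-coding genes.

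The 19 gene lists, the tests and the naming rule were fixed before the data were examined. Each list was tested with a one-sided Fisher exact test for more members with a site than among all RefSeq genes, with the conditional odds ratio and its exact interval, and p-values were adjusted over the 19 lists by the Benjamini-Hochberg method at 0.05. Protein lists kept protein-coding genes only, which left out 56 matches of the initiation factor rule and 128 of the RNA-binding protein rule, and RPS4Y1 and RPS4Y2 were left out. The list of mitochondrially encoded genes took all 37 genes of the mitochondrial genome, since the table writes their symbols without a prefix. As alternatives the background was restricted to protein-coding genes, or matched on class (protein-coding, long noncoding, other) and 10 length classes, with a Mantel-Haenszel odds ratio and an exact p. Shares of sites have exact binomial intervals, site counts exact Poisson intervals, and strand shares and positions along the transcript intervals from 2000 redraws of genes, all at 95%. Sites of 1 gene are not independent, so the binomial and Poisson intervals are too narrow.

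The list test was tested on simulated data, with 100 random lists of 200 protein-coding genes for each true odds ratio over the 59716 genes. With a true odds ratio of 1, the test against all genes called 77 lists and the matched test 8. With a true odds ratio of 3, the matched test called all 100, with a median estimate of 2.90. The test against all genes therefore calls protein-coding lists that carry no difference, and matched values stand beside it where they change a call. Calls on simulated lists were counted on p-values without adjustment. The fixed lists of protein-coding genes were smaller, with at most 113 members, and 21 for proline and glutamate metabolism. How often the matched test would call a true difference in lists of those sizes was not simulated, so a list that did not pass can still differ.

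The named genes are ALDH18A1, the 10 assigned genes with most sites, and in each list up to 4 members with most sites, ties broken by name. XIST and Y-linked genes were left out, and some genes that the rule names are not reported here. The rule also asked for the 10 sites of highest score, which could not be taken without a score. Alternatives for region shares and gene counts used narrower or wider sites, each gene counted once, each pair on both strands counted once, sites of 1 strand, and the list without the 5 genes with most sites. Analyses used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures matplotlib 3.10.9.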

Results

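RNA sites of P5CS were mapped in NCI-H1299 cells, an established line of human lung carcinoma. P5CS is the enzyme that makes pyrroline-5-carboxylate from glutamate on the way to proline, and its gene is ALDH18A1. LACE-seq amplifies cDNA ends from RNA that was pulled down with an antibody, so that the places where the protein sat can be read on the genome. The 4 libraries fall into 2 groups, 2 made with an antibody against P5CS and 2 with IgG, an antibody with no chosen target. The question named in the series title is whether P5CS acts as an RNA-binding protein in translation. The data analysed here are 1 list of 17625 sites on the human genome build hg38, each with a strand, a region and an assigned gene. The list carries no value per library and no score. The anti-P5CS and IgG libraries were therefore not compared here, the depth of each library is unknown, and no value below has a replicate error. Whether sites also seen with IgG were taken out of the list is not given in the sources used here, so a site below is a listed site and not a measured excess over IgG. Intervals are 95% intervals that cover counting error only.

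Introns and exons held most of the sites. Introns had 6725 sites, 38.2% of the list (exact binomial interval 37.4 to 38.9), and exons outside the untranslated regions had 6381, or 36.2% (35.5 to 36.9). Intergenic positions held 2603 sites, or 14.8% (14.2 to 15.3). The 5' UTR class held 1094 sites, or 6.21% (5.86 to 6.57), and the 3' UTR class held 822, or 4.66% (4.36 to 4.99). Of the 5' UTR sites, 334 are annotated as promoter in the list's own annotation text. The classes include noncoding transcripts, so exons are not a measure of coding sequence, and 186 of the 5' UTR sites overlapped no protein-coding RefSeq gene. Of all 5' UTR sites 13 lay in 45S ribosomal RNA genes. Without the 5 assigned genes with most sites, introns fell to 29.3% and exons rose to 41.2%, and exons also exceeded introns among narrower sites (38.2% against 36.2%) and with each gene counted once per region (39.5% against 27.1%). The order of these 2 classes is therefore not settled. The length of each region in the genome was not analysed here, so these shares do not show enrichment in any region.

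Sites were crowded toward the start of the assigned transcript, and less strongly toward its end. Of the 15022 sites inside their assigned gene, 16.2% lay in the first of 10 equal parts of the transcript span (interval from redrawing genes 14 to 18). The last part held 11.5% (9.78 to 13.2), and each part between them held 8.25% to 9.53%. Without the 5 genes with most sites the first part held 17.5% (16 to 19) and the last 12.8% (11.7 to 13.9). The list gives each site's distance to a transcript start, and an assignment by the nearest start would itself raise the first part. Among sites that overlap 1 RefSeq gene, placed along its RefSeq span, the first part held 17.03% (15.1 to 19.2) and the last 13.8% (12.3 to 15.5) of 8778 sites. Gene strands came from the list, so 8617 of these sites were assigned to that same gene and only 161 to another gene or none. Another 2209 such sites were left out because the list gives no strand for their gene. The check can therefore remove little of a part played by the assignment.

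Sites opposite to the strand of the assigned gene outnumbered those on it. Over the whole list 10277 sites, or 58.3% (57.1 to 59.6), lay on the opposite strand. The share was 59.2% in exons, 58.3% in introns, 62.0% in the 5' UTR, 61.9% in the 3' UTR and 53.6% in intergenic positions. In addition, 6922 sites, or 39.3% of the list, formed 3461 pairs with identical coordinates on both strands. The share of sites in such pairs was 48.9% in the 3' UTR, 48.5% in exons, 46.1% in the 5' UTR, 31.8% in introns and 30.3% in intergenic positions. Without the pairs, 63.7% (61.3 to 66.1) of sites were opposite to the gene. The strand of a site was therefore not used to assign it to a gene in any count below.

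**Figure D1:**
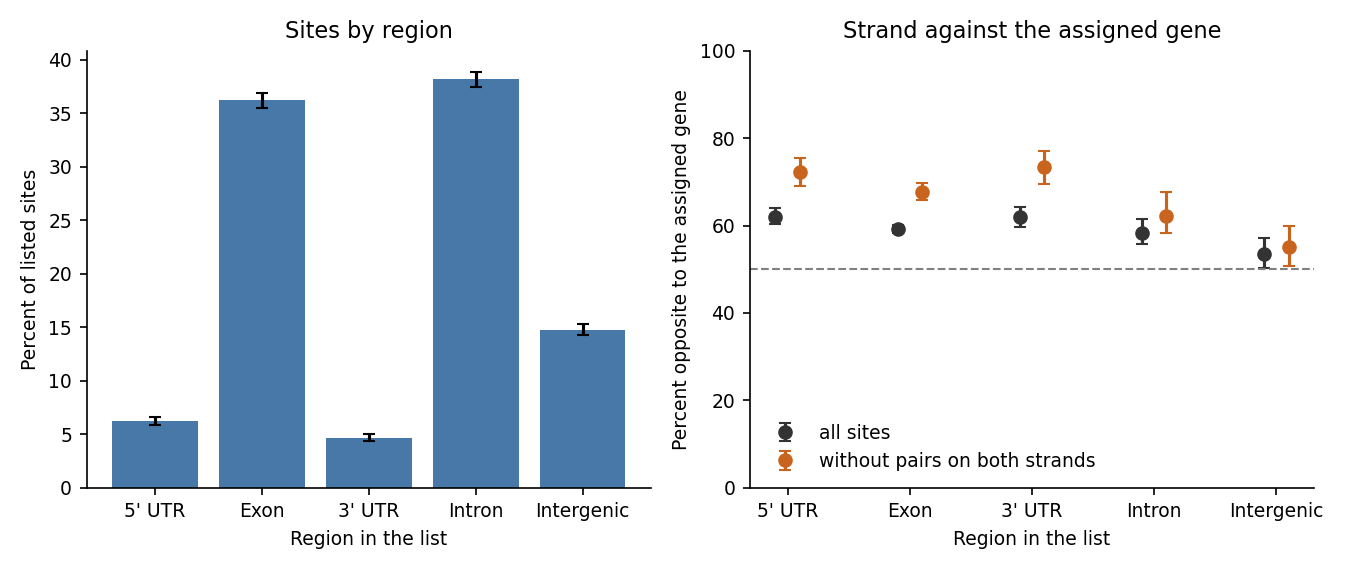
Left, the percent of the 17625 listed sites in each region, with exact binomial 95% intervals; right, the percent of each region's sites opposite to the strand of the assigned gene, with 95% intervals from redrawing genes, for all sites and without pairs on both strands, and a dashed line at 50. Introns (38.2%) and exons (36.2%) hold most sites, and in all 5 regions more sites lie opposite to the gene than on its strand.

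The site counts were very uneven between genes. The list names 4340 assigned genes, of which 1856 (42.8%) had 1 site, the median was 2, and 289 had 10 or more. The 5 genes with most sites held 2457 sites, or 13.9% of the list. They were LINC00665, a long noncoding RNA gene on chromosome 19 with 725 sites (exact Poisson interval 673 to 780), ENSG00000267605.8 on chromosome 19 with 629 (581 to 680), ENSG00000280441.3 on chromosome 21 with 453 (412 to 497), and CCDC200 on chromosome 17 and SNHG27 on chromosome 4 with 325 each (291 to 362). Most of these lay in introns, with 704 intronic sites in LINC00665, 618 in ENSG00000267605.8, 395 in ENSG00000280441.3, 276 in CCDC200 and 286 in SNHG27. Of the sites assigned to ENSG00000280441.3, 165 lay in 45S ribosomal RNA genes, 150 of them annotated as intronic, and these are counted again with the 45S genes below. The assigned name does not always match the nearest RefSeq gene. Of the 725 sites assigned to LINC00665, between positions 36256320 and 36327800, 677 lay in the RefSeq span of CYKILR.

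NTM, which encodes the cell adhesion protein neurotrimin, had 173 sites on chromosome 11 between 131370980 and 132162580, 169 of them intronic. ENSG00000278996.1 on chromosome 21 had 155 sites, 70 of them in a 45S gene and counted again below. NEAT1, the long noncoding RNA that builds nuclear paraspeckles, had 104 sites on chromosome 11, 99 of them exonic. PLEC, which encodes the cytoskeletal linker plectin, had 100 sites on chromosome 8, 87 of them exonic. BRF1, a subunit of the RNA polymerase III initiation factor, had 99 sites on chromosome 14, all intronic, a count shared with ENSG00000286155.1 on chromosome 21. Among protein-coding genes further down, AXL had 93 sites, EEF1D 75 and FASN 38. Of these, AXL and FASN fall outside the naming rule and were chosen after their values were seen, and EEF1D is named again with its list below. AXL is a receptor tyrosine kinase and FASN the fatty acid synthase. By chromosome, chromosome 19 had most sites, 2796 or 15.9% (15.3 to 16.4), of which 1442 remained without the 5 genes with most sites. Chromosome 19 then ranked 2, behind chromosome 1 with 1813.

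**Figure D2:**
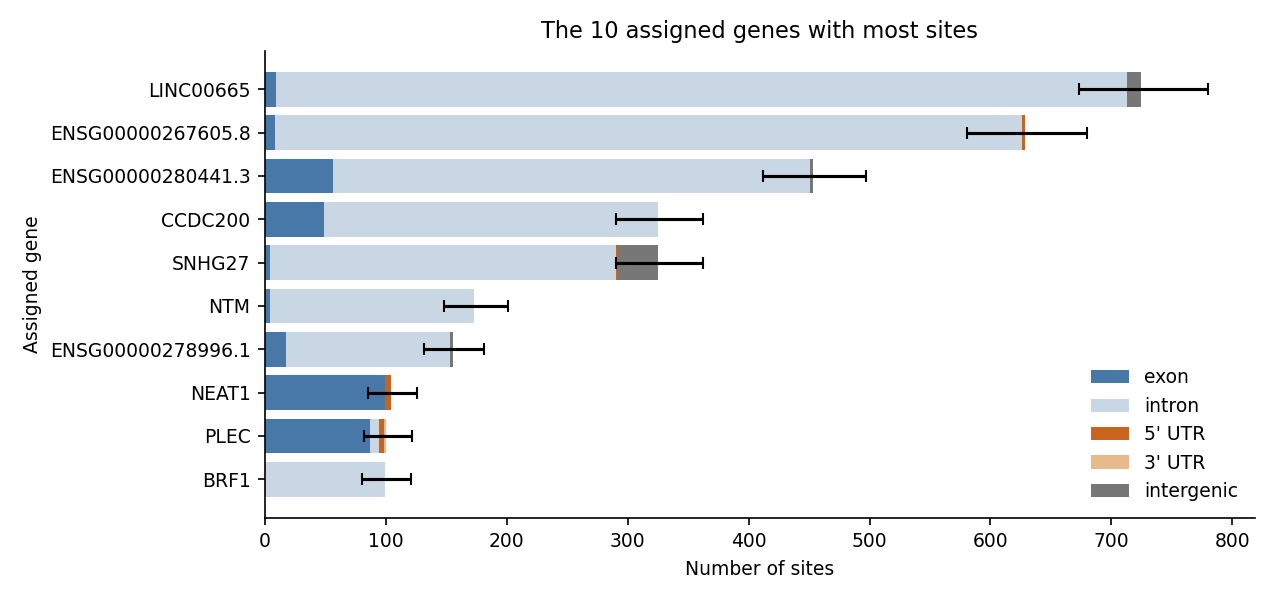
Number of sites of the 10 assigned genes with most sites, coloured by region, with exact Poisson 95% intervals on each total. LINC00665 leads with 725 sites, the 7 genes at the top hold mostly intronic sites, and NEAT1 and PLEC hold mostly exonic ones.

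ALDH18A1 itself had no site. Its RefSeq span on chromosome 10, positions 95605941 to 95656711, overlapped 0 listed sites, and 0 sites were assigned to it. Of 2277 protein-coding genes of similar length, 340 (14.9%) had a site.

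Ribosomal RNA genes on chromosome 21 were covered almost end to end. The 45S genes, which are transcribed into the precursor of 18S, 5.8S and 28S ribosomal RNA, had 87 sites in RNA45SN1, 77 in RNA45SN2 and 86 in RNA45SN3, and 0 in RNA45SN4, which the reference table places on chromosome 22. These sites covered 96.7% of RNA45SN1 (chromosome 21, 8433222 to 8446572), 95.7% of RNA45SN2 (8205988 to 8219302) and 93.2% of RNA45SN3 (8389035 to 8402343). Coverage ran through the spacers as well as the mature parts, with 98.3% of the 28S part and 95.8% of the 5' external spacer of RNA45SN1 covered. The 3' external spacer was covered less, at 65.4% in RNA45SN1, 57.3% in RNA45SN2 and 46.0% in RNA45SN3. Of the 58 sites wider than 500 bases in the list, 54 lay on chromosome 21. In RNA45SN1, RNA45SN2 and RNA45SN3 the 18S part lies at lower positions than the 28S part, so the RNA runs along the plus strand. In RNA45SN1 the minus-strand sites, opposite to the RNA, covered 96.7% and the plus-strand sites 17.6%. In RNA45SN3 they covered 93.2% and 82.5%. In RNA45SN2 the order was the other way, with 85.8% for the minus strand and 92.1% for the plus strand. The 45S copies are nearly identical and reads cannot be placed in one of them with certainty, so the counts per copy are uncertain.

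**Figure D3:**
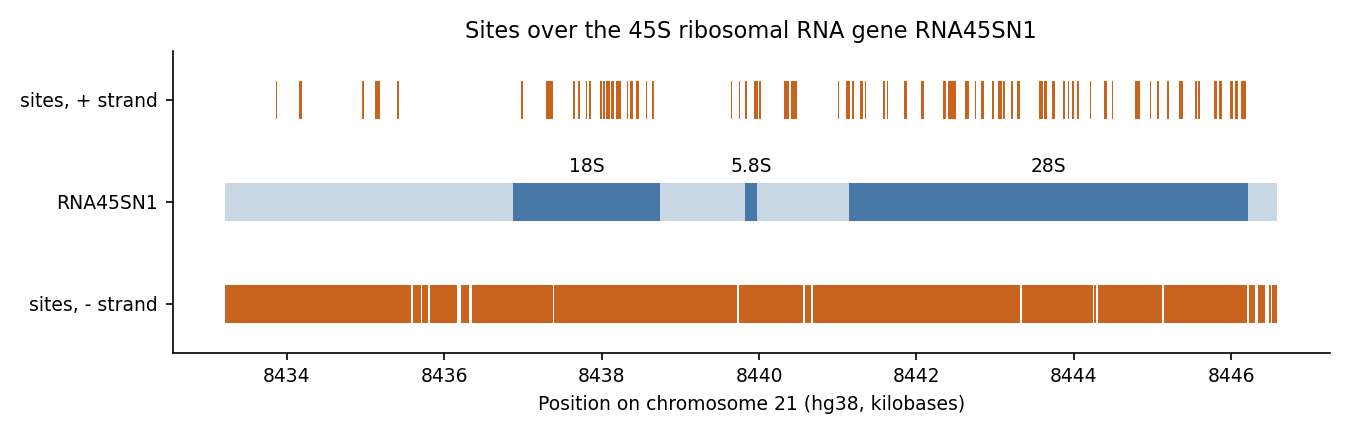
Map of the 45S ribosomal RNA gene RNA45SN1 on chromosome 21 (hg38, position in kilobases), with mature 18S, 5.8S and 28S parts in dark blue, spacers in pale blue, and sites on the plus and minus strand in orange above and below. The RNA runs along the plus strand. Minus-strand sites, opposite to it, cover 96.7% of the gene and plus-strand sites 17.6%.

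Other abundant structured RNAs also carried sites. Of the 3006 genes and pseudogenes on the list of small structured RNAs, 530 (17.6%) had a site, with an odds ratio of 2.65 (2.39 to 2.92) against all 59716 RefSeq genes (one-sided Fisher exact test, adjusted exact p = 1.68e-68) and 4.04 against genes of the same class and length. It was 1.25 with only sites that overlap 1 RefSeq gene and 5.30 with only wider sites. The share differed between families. All 17 genes of 5S ribosomal RNA, all 4 of U1 and all 5 of U6 small nuclear RNA had a site. In a separate count, 119 of 443 nuclear tRNA genes (26.9%) had one. Most of these 119 are not on the list, whose rule missed their symbols. At the U2 small nuclear RNA cluster on chromosome 17, positions 43233790 to 43300231, where the CCDC200 sites lie, 13 of 13 snRNA genes had a site. All of these but RNU2-1 carry LOC symbols and are outside the list. The 4 Y RNA genes had none. Most members of this list have near-identical copies elsewhere, and a site in one copy does not show which copy was bound. Of the 13 members found of the list of abundant nuclear long noncoding RNAs, 10 had a site (odds ratio 38.4, 9.89 to 217, adjusted exact p = 7.62e-09), with 108 sites in the RefSeq span of NEAT1, 61 in MALAT1, 16 in SNHG1 and 10 in GAS5. That odds ratio ranged from 22.2 to 72.2 over the alternatives.

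Nearly every mitochondrially encoded gene had a site. Nuclear-encoded respiratory chain subunits had sites about as often as genes of the same class and length (7 against 7.30 expected). The mitochondrial and nuclear genes were not tested against each other. Of the 37 genes of the mitochondrial genome, 35 had a site (odds ratio 203, 52.1 to 1742, adjusted exact p = 1.89e-35). The odds ratio was 25.1 with only sites that overlap 1 RefSeq gene and 9.75 by the gene assignment of the list, both past the threshold. These genes lie side by side on 1 small genome and can share a site. Their site counts added to 288, whereas the genome held 257 sites. The genes are therefore not independent, and the interval and p overstate the certainty. COX1, a subunit of cytochrome c oxidase, had 32 sites, and the NADH dehydrogenase subunits ND5, ND4 and ND1 had 27, 26 and 23. Sites covered 95.4% of the bases of the 2 mitochondrial rRNA genes and 68.3% of those of the 13 protein-coding genes. Among nuclear-encoded respiratory chain subunits, 7 of 74 had a site (odds ratio 1.20, 0.466 to 2.62, adjusted exact p = 0.480), and ATP5F1A, COX6A1, NDUFV1 and UQCRC1 had 2 sites each. Their odds ratio was 0.669 against protein-coding genes and 0.955 matched on class and length, so its direction depends on the background. Among mitochondrial ribosomal proteins, 3 of 80 had one (odds ratio 0.448, 0.0904 to 1.36, adjusted exact p = 1), MRPL48 with 4 sites, MRPS31 with 2 and MRPS21 with 1. Against protein-coding genes their odds ratio was 0.249 (0.0502 to 0.756), an interval below 1, and matched it was 0.334.

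Genes for cytosolic ribosomal proteins, translation factors and RNA-binding proteins had sites more often than other genes. Of 86 genes for cytosolic ribosomal proteins, 42 (48.8%, 37.9 to 59.9) had a site, including RPL13A with 10, RPL3 with 8 and RPL13 with 6. The odds ratio was 11.1 (7.07 to 17.3, adjusted exact p = 8.24e-23). Set directly against the mitochondrial ribosomal proteins, a comparison chosen after the values were seen, the odds ratio was 24.1 (7.06 to 128; two-sided Fisher exact test, p = 8.47e-12), and it was 11.6 with only sites that overlap 1 RefSeq gene and 9.14 with only wider sites. Of 61 translation initiation factor genes 22 had a site (odds ratio 6.52, 3.68 to 11.3, adjusted exact p = 2.68e-09), among them EIF3B with 19 sites and the helicases EIF4A1 and EIF4A2 and the poly(A)-binding protein PABPC1 with 15 each. Of 20 elongation and termination factor genes 7 had a site (odds ratio 6.21, 2.10 to 16.7, adjusted exact p = 0.00133), with 75 sites in EEF1D, 21 in EEF2, 12 in EEF1A1 and 4 in TUFM, a mitochondrial factor, so this list is not limited to the cytosol. The 75 sites assigned to EEF1D were mostly intronic, with 52 in introns, 14 in the 5' UTR class and 9 in exons. Of 113 genes for RNA-binding proteins of mRNA metabolism 42 had a site (odds ratio 6.86, 4.56 to 10.2, adjusted exact p = 2.03e-17), including PTBP1 with 13 and SRSF5 with 12. PABPC1 is on this list as well.

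Against genes of the same class and length these 4 lists also passed, at odds ratios of 11.2 for cytosolic ribosomal proteins, 3.91 for initiation factors, 3.37 for elongation and termination factors and 4.06 for RNA-binding proteins. Over all alternatives their odds ratios ranged from 5.28 to 14.4, from 3.64 to 10.9, from 3.37 to 11.3 and from 3.84 to 10.3 in that order, all past the threshold. The lowest was with only wider sites for ribosomal proteins. Aminoacyl-tRNA synthetases, the enzymes that charge tRNAs, had a site in 7 of 39 genes (odds ratio 2.52, 0.938 to 5.82, adjusted exact p = 0.0484), with 2 sites each in AARS2 and IARS1 and 1 each in CARS1 and NARS2. Matched on class and length, their odds ratio was 1.33 (adjusted exact p = 0.424).

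Glycolysis and growth genes had sites more often than other genes. Of 18 glycolysis genes 7 had a site (odds ratio 7.33, 2.41 to 20.7, adjusted exact p = 0.000711; matched 4.55, adjusted exact p = 0.00881), with 12 sites in GPI, 8 in GAPDH, 4 in ENO1 and 2 in PKM. Of 29 cancer growth and cell cycle genes 10 had a site (odds ratio 6.07, 2.52 to 13.7, adjusted exact p = 0.000138; matched 3.46, adjusted exact p = 0.00853), with 9 in EGFR, 8 in MKI67, and 7 each in CDK6 and MYC. In the amino acid and integrated stress response list 7 of 23 had a site (odds ratio 5.04, 1.75 to 13.0, adjusted exact p = 0.00279). The amino acid transporter SLC7A5 had 31, its partner SLC3A2 had 4, GCN1 had 3 and ATF5 had 2. Against protein-coding genes alone that list missed the threshold (odds ratio 2.81, adjusted exact p = 0.0634). Of 26 mTOR signalling genes 6 had a site (odds ratio 3.46, 1.14 to 8.93, adjusted exact p = 0.0235), with 20 in AKT1, 16 in AKT2, 4 in RPTOR and 2 in MTOR, and with matching the odds ratio was 1.89 (adjusted exact p = 0.250).

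Genes of proline and glutamate metabolism, the pathway of P5CS, did not pass the test. Of 21 genes 4 had a site (odds ratio 2.71, 0.663 to 8.31, adjusted exact p = 0.111). The glutamine and amino acid transporters SLC1A5 and SLC38A2 had 10 and 9 sites, and PRODH2 had 1. By the gene assignment of the list the odds ratio was 4.22 (adjusted exact p = 0.0306), against protein-coding genes it was 1.51, and matched on class and length 1.72. Collagens and prolyl hydroxylases, whose products are rich in proline or modify it, had a site in 12 of 55 genes (odds ratio 3.22, 1.54 to 6.22, adjusted exact p = 0.00217), with 19 in P4HB, 7 in COL18A1, 3 in COL6A2 and 2 in COL22A1. Matched on class and length the odds ratio was 1.14 (adjusted exact p = 0.494). Replication-dependent histones had a site in 5 of 69 genes (odds ratio 0.899, 0.282 to 2.21, adjusted exact p = 0.732), with 4 in H2BC5, 2 in H2BC4 and 1 each in H2AC11 and H2AC12. Their odds ratio was 0.4998 against protein-coding genes and 1.51 matched on class and length, so its direction depends on the background. Markers of other cell types did not pass the test. Of 10 fibroblast markers 1 had a site, 1 site in DCN (adjusted exact p = 0.671), and of 10 blood cell markers 0 had one (adjusted exact p = 1).

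Over the 19 lists 13 passed against all RefSeq genes, and 10 passed with matching on class and length. Longer genes had sites more often, from 4.49% of protein-coding genes in the shortest of 10 length classes to 25.9% in the longest. Expression in these cells was not measured here, so the tests do not separate abundant transcripts from transcripts chosen by P5CS, and genes are not replicates.

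**Figure D4:**
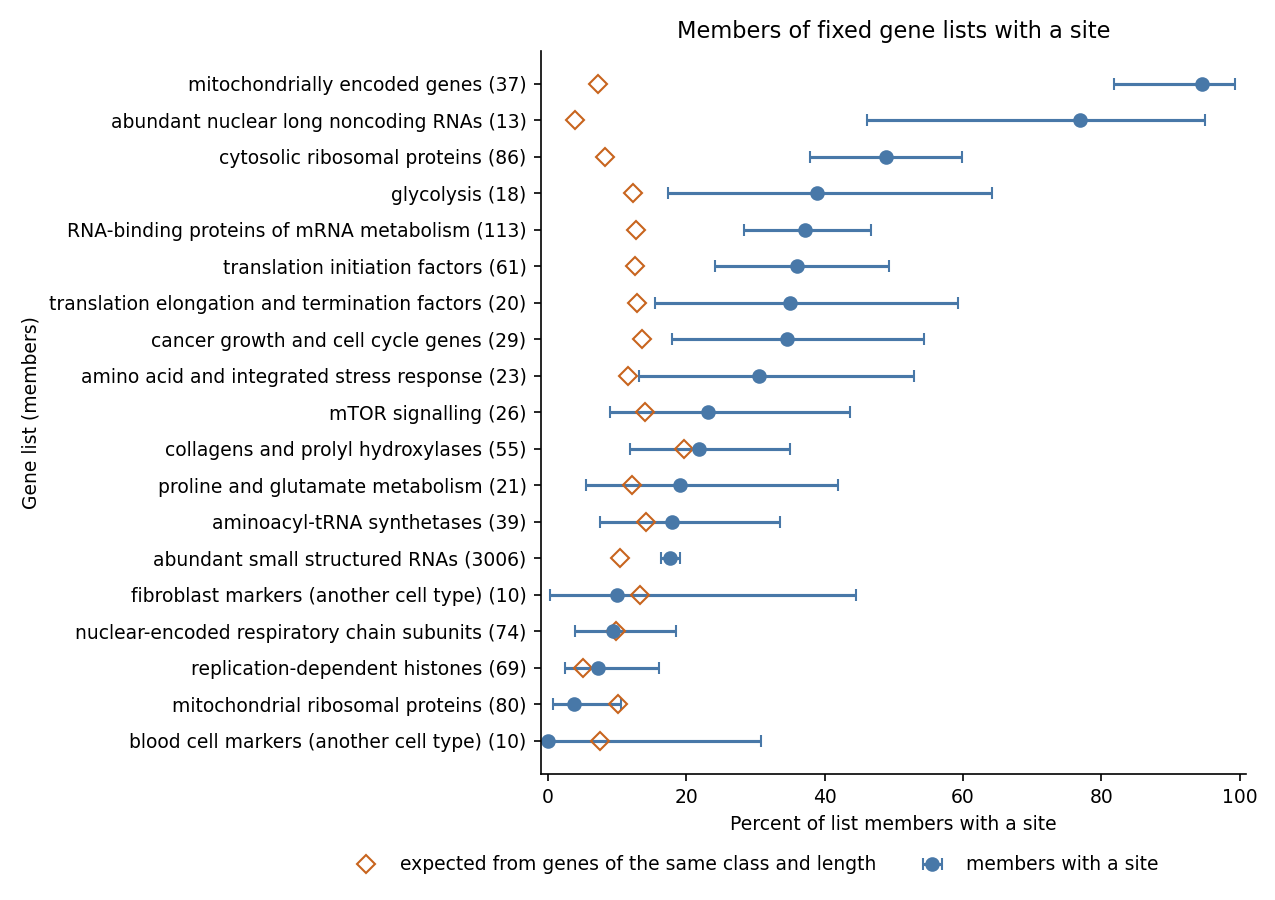
Percent of the members of each fixed gene list with a listed site (blue points, exact binomial 95% intervals; number of members in parentheses) and the percent expected from genes of the same class and length (open diamonds). Cytosolic ribosomal proteins (48.8%) lie above their expected value, whereas the interval of mitochondrial ribosomal proteins (3 of 80 with a site) holds it.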

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

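The alternatives that count pairs once, drop the 5 genes with most sites, keep 1 strand, use the list's own gene assignment or keep sites that overlap 1 RefSeq gene were chosen after seeing the data, as were those on wider sites for gene counts, strand and gene lists and all those on the position in the transcript. The same holds for the strand shares without pairs and with each gene counted once, and for chromosome 19 among wider sites. Of the values that answer a comparison, 121 stayed on the same side of the threshold or within their interval, 37 moved, 12 were weaker, 1 was stronger and 1 was reversed, and where not stated the cause was not tested. For single named genes 65 values stayed within 1.5 times and 89 were lower, 70 of these with only wider sites and 19 with each pair counted once. Both alternatives leave fewer sites by construction. With each pair counted once 58 values stayed, whereas RPL13A fell from 10 to 6, EEF1A1 from 12 to 7, P4HB from 19 to 12 and MYC from 7 to 4. No paired analysis was possible because the list holds no value per library. For the same reason the planned tests of anti-P5CS against IgG, the overlap of replicates, the stricter threshold by score and the estimated correlation were not run. The words of sequence were not analysed, as no genome sequence was used. Unknown depth limits every absence in the list.

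By region, only sites wider than the median gave 5' UTR 7.12%, exon 30.4%, 3' UTR 2.47%, intron 43.9% and intergenic 16.2%. Narrower sites gave exon 38.2%, 3' UTR 5.42% and intron 36.2%. Counting each gene once per region gave 10.7%, 39.5%, 7.22%, 27.1% and 15.5% for 5' UTR, exon, 3' UTR, intron and intergenic. Without the 5 genes with most sites these were 7.19%, 41.2%, 5.42%, 29.3% and 16.8%. Counting each pair once gave exon 34.1%, intron 39.9% and intergenic 15.6%. Sites on the strand of the gene gave 5' UTR 5.66%, exon 35.5%, 3' UTR 4.26% and intergenic 16.4%, and opposite sites gave 5' UTR 6.60% and intergenic 13.6%. RefSeq spans held 78.8% of sites against 85.2% inside the assigned gene. Sites opposite to the gene were 63.7% without pairs, 56.3% among wider sites and 60.4% with each gene counted once. The last of 10 parts of the transcript held 13.8% among sites that overlap 1 RefSeq gene, placed along its span. Chromosome 19 ranked 3 per annotated gene, 2 per megabase and 2 without the 5 genes with most sites. The 5 genes with most sites held 15.5% with each pair counted once and 30.4% among wider sites.

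Against protein-coding genes 6 of the 16 lists tested passed, not 13 of 19. There the odds ratio was 1.40 for aminoacyl-tRNA synthetases, 1.79 for collagens and prolyl hydroxylases, 2.81 for the stress response and 1.92 for mTOR signalling, none past the threshold. Matched on class and length it was 1.33 for the synthetases, 1.14 for collagens and 1.89 for mTOR signalling. With genes of at least 2 sites it was 1.06 for the synthetases and 1.97 for collagens. With only wider sites it was 2.59 for collagens and 2.04 for the stress response, and for the synthetases it turned to 0, since no member kept a site. Proline and glutamate metabolism passed by the list's own gene assignment, at 4.22.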

Other observations

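The family comparison, the site spacing, the tests on overlapping genes, the strand column by class of site and multi-copy genes, the values at further lags and the U2 distances were chosen only after the sites were seen; the other tests below were fixed before their values were seen. Gene families were formed from the letters at the start of the symbol, 154 families of at least 15 protein-coding genes, each set against genes of the same length with a two-sided exact test. Beyond the ribosomal protein and initiation factor families, SPDYE genes, a multi-copy set of paralogs, had a site in 11 of 19 (odds ratio 12.6, adjusted exact p = 3.48e-05). Olfactory receptor genes (OR) had one in 2 of 392 against 28.1 expected (odds ratio 0.0625, adjusted exact p = 1.33e-08). Zinc finger genes named ZNF had one in 46 of 517 (odds ratio 0.634, adjusted exact p = 0.0695), which missed the threshold. Symbols with the letter C before a number, a mixed set and no family, had one in 12 of 254 (odds ratio 0.376, adjusted exact p = 0.00684).

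Pseudogenes of abundant small RNAs carried sites too, to different extents. A site lay in 50 of 115 U1 pseudogenes (43.5%), 33 of 69 U2 pseudogenes (47.8%) and 94 of 293 7SK pseudogenes (32.1%). It lay in 30 of 684 7SL pseudogenes (4.39%), 5 of 89 U4 pseudogenes (5.62%) and 0 of 75 Y RNA pseudogenes. U6 pseudogenes, at 159 of 1277 (12.5%), and 5S pseudogenes, at 76 of 510 (14.9%), lay between. Among all RefSeq genes of the pseudogene class 924 of 15580 (5.93%) had a site. Of 13 nuclear genes that resemble the mitochondrial 16S rRNA gene (MT-RNR2-like), 12 had a site, 100 sites in all. C/D box snoRNA genes had a site in 86 of 362 (23.8%) and H/ACA box snoRNA genes in 22 of 182 (12.1%). In BRF1, with 98 of its 99 sites in intron 2, 58 of 79 gaps longer than 2 steps of the grid between neighbouring starts measured 100 bases (73.4%), against 33.3% for the commonest gap in the next of 35 genes examined.

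The excess of sites opposite to the assigned gene was weighed first. Assignment to the wrong one of overlapping genes is argued against, since 61.3% (60.5 to 62.1) were opposite among the 8622 sites that overlap the assigned RefSeq gene alone. A strand column that runs opposite to the RNA stays open. The lowest of 4 classes of unpaired sites, introns of coding genes, had 68.2% opposite (65.3 to 70.9), but this repeats the excess itself and decides nothing. In mitochondrial rRNA and protein-coding genes of the plus strand, whose RNA comes mostly from that strand, 45.1% (39.6 to 50.01) of 144 unpaired sites lay on the minus strand. The interval reaches 50%, so by its prediction this test does not decide either. It lies below the 65.3 to 70.9 of coding introns, but site counts in densely covered genes cannot be set against these. Sites covered 68.3% of the bases of mitochondrial protein-coding genes and 95.4% of those of the rRNA genes. Under such coverage 1 strand can merge into few wide sites. In RNA45SN1 18 minus-strand sites covered 96.7% and 69 plus-strand sites 17.6%. Whether these mitochondrial genes share the excess is therefore not shown. The 45S genes, whose RNA runs along the plus strand, do not decide either. Minus-strand sites covered more than plus-strand sites in RNA45SN1 and in RNA45SN3 (93.2% against 82.5%), but less in RNA45SN2 (85.8% against 92.1%). Transcription from both strands was not tested, and the design gives no biological explanation to test.

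For the pairs with identical coordinates on both strands, chance under even placement is argued against, since genes with 3 or more sites held 2743 pairs and 100 random placements gave at most 186. The minus-strand sites were placed evenly between the first and last site of each gene. Crowding of sites within a gene was not kept, so these placements can give too few pairs. Whether reads without strand information add to the pairs is not settled. In single protein-coding genes 75.3% of wider sites overlapped a site on the other strand against 54.4% of the narrowest. The difference of 20.9 exceeded the 14.7 that random placement gave at most, as the prediction asked. Random placement itself gave mean shares of 27.4% and 14.4%, far below those seen. Differences at such unlike levels cannot be compared directly, so no conclusion is drawn. Of the 6922 sites in pairs, 8.67% (7.30 to 10.2) overlapped a gene of the small structured RNA list or the mitochondrial genome, so most pairs lay outside these genes. The 2 sets held only 1442 and 288 sites, so a high share could not arise. Other multi-copy genes, such as 7SK pseudogenes, MT-RNR2-like genes and most nuclear tRNA genes with a site, are not among them. The share therefore does not decide whether multi-copy RNA genes as a whole are the cause. Sites in 45S, 5S and U2 genes were in pairs at 16.7% (8.61 to 44.4) against 46.0% (44.3 to 47.6) in single protein-coding genes, with intervals that overlap. A pair needs identical ends, and in RNA45SN2, covered at 92.1% on the plus and 85.8% on the minus strand, 2 of 77 sites were in pairs. The comparison therefore cannot decide, and a share of the pairs from these genes stays open. No biological explanation was tested.

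The crowded loci may be tandem repeats, whose copies would collect sites at a fixed distance. The highest autocorrelation of site coverage was 0.590 at 2540 bases for LINC00665, 0.422 at 2480 for SNHG27, 0.284 at 10100 for ENSG00000267605.8 and 0.227 at 6160 for CCDC200, each above the highest of 100 random placements (0.120, 0.133, 0.195 and 0.110). SNHG27 had 0.0239 at 1240 bases and 0.342 at 4960, as a repeat would give, whereas LINC00665 had 0.461 at 1270 bases, so its unit is not settled. CCDC200 had -0.0493 at 3080 bases and 0.0751 at 12320, the latter lower than its 0.227 at 6160. The random values are the highest over all lags, so a value at 1 chosen lag cannot be judged against them. At the CCDC200 locus 5 of the 12 distances between the starts of neighbouring U2 genes measured 6131 to 6161 bases, close to the lag of 6160, whereas the others differed, so copies of the U2 unit fit there without an even spacing throughout. The test is not specific to these loci: of 4 comparison genes PLEC (0.129) and NEAT1 (0.138) stayed within random placement, but BRF1 (0.658 at 1120 bases) and AXL (0.175) exceeded it. BRF1 had 73.4% of its gaps at 100 bases and 0.508 at 2240 bases, so its sites are evenly spaced themselves. Only AXL therefore bears on whether the test also calls loci without even spacing. Repeat annotation was not used here, and no biological explanation was tested.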
